A study of Arabidopsis thaliana with 5 samples.

How the data were processed

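Transcript levels were measured on Affymetrix ATH1 arrays in Arabidopsis thaliana roots. Seedlings grew for 5 days at pH 5.7 and were then held at pH 4.6 for 24 h, per the labels. One group of 3 samples held cells freed from their walls by protoplasting and passed through a cell sorter, with RNA from about 50000 cells each. The other group of 2 samples held intact whole roots, labelled from 1 µg of total RNA with a single-cycle protocol, per the labels' protocols. The labelling of the sorted samples was given as the manufacturer's standard protocol.

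The values are intensity values that the authors deposited, 1 linear signal per probe set and array, made with MAS5 per the submitters' processing notes. The mean signal after trimming 2% of probe sets at each end was 250 on each of the 5 arrays, so each array had been scaled to 1 target. The value table used here gives no detection calls, and the software version was not given in the sources used here. No value lay at or under 0. Because arrays hold no counts, their number limits the precision: 3 against 2 samples.

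From there, log2 of the deposited values was used with no further normalization. The 64 control probe sets were left out of the tests. Of the remaining probe sets, the 40% with the lowest mean log2 value (9099 probe sets, mean signal below 43.3) were left out, and 13647 were tested. The test was limma 3.58.1 (R 4.3.3), lmFit and eBayes with a mean-variance trend, with group as the sole factor and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are sorted protoplasts minus whole roots. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

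Probe sets were named through the platform annotation supplied with the series. It named 1 gene for 13513 of 22810 probe sets, several genes for 503 and none for 8730. Of the single-gene probe sets, 13436 matched the RefSeq gene table by gene ID, 18 matched a mitochondrial gene by symbol and 59 matched neither. Probe sets with several genes or none were counted but not named. Gene lengths came from the same gene table and hold introns. Because no build is given for the probe sets, no coordinates are printed.

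Gene lists were written from textbook knowledge before the data were examined, and so were the design, the rule for named genes and most alternatives. The annotation named few members of these 28 planned lists, and 5 of them (ethylene synthesis and response, indole defence compounds, aquaporins, nutrient uptake and assimilation, suberin synthesis) had no named probe set. A further 21 lists were therefore added after the annotation was read and before any fit. Each gene was represented by its probe set with the highest mean. Lists with at least 3 tested genes were tested with camera in limma (preset correlation 0.01), and adjusted with Benjamini-Hochberg separately over the planned and the added lists. Named genes were the 6 largest rises and 6 largest falls among single-gene probe sets past the threshold without overlap between the groups, and for each list the 2 members with the largest change in the direction that more members took (or the member with the smallest adjusted p where none passed).

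Alternatives were median centring, quantile normalization, a pseudocount of 32, no filter, a filter at 60%, no mean-variance trend, the replicate number as a block, a test against a log2 fold change of 1, an estimated camera correlation, fry, and leaving out each sample. With an estimated correlation, camera also tests on the 3 residual degrees of freedom, so a loss there can come from that alone. A removal of the trend of fold change with gene length (a loess curve) was added after seeing the data. On simulated data for this comparison with 13647 probe sets, the test recovered 90% of 100 probe sets changed by log2 1 and 100% of 100 changed by log2 2, with 6 false calls. In that simulation the spread depended on signal alone, and 200 probe sets were changed, while 60.6% of tested probe sets were called in the data. These rates may therefore be too favourable for the data. The list test found 10 of 10 shifted lists and 0 of 30 others among 7332 simulated genes. These genes varied independently, unlike lists such as ATG8 (estimated correlation 0.310), so the result does not cover correlated genes. Genes outside the shifted lists also had no group difference, unlike in the data, so the result does not cover lists set against many changed genes. On simulated values with a length trend and no changed gene, calls went from 2111 of 7327 to 0 when the trend was removed.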

Results

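The series compared 3 samples of protoplasted and sorted whole-root cells with 2 samples of intact whole roots, all at pH 4.6 for 24 h. The comparison asks how far freeing root cells from their walls and sorting them changes the transcript profile of the root. Signals correlated across probe sets at a mean r of 0.966 among the sorted samples, 0.980 between the whole-root samples and 0.680 between the groups. Sorted replicate 1 stood apart, with r of 0.954 and 0.956 to sorted replicates 2 and 3, against 0.987 between those 2. Genes are not independent replicates, so these values describe the arrays.

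All 3 tested heat shock genes (of 5 named) and 6 of 9 mitochondrion-encoded genes were higher in the sorted protoplasts. Of 5 tested genes on an overlapping list of small heat shock proteins, 3 were higher and 2 lower. Neither the heat shock nor the mitochondrion-encoded list passed camera with an estimated correlation, which also leaves the test few degrees of freedom (adjusted p = 0.389 for each). Lower were 6 of 7 nuclear photosynthesis genes, all 3 tested extensins of the cell wall, all 4 tested CYP71B cytochromes P450 and all 9 ATG8 genes of autophagy. These lists did not pass either with the correlation estimated (adjusted p = 0.521 with an estimated correlation for each), and the CYP71B call was also lost with no filter (adjusted p = 0.0532). The largest fall was that of AT4G38080, from a signal of 4775 ± 62.0 (SD, n = 2) in whole roots to 4.67 ± 6.32 (SD, n = 3) in sorted protoplasts. AT5G19110, an aspartyl protease family gene, had the highest fitted log2 fold change, going from 14.62 ± 3.499 (SD, n = 2) to 1164 ± 204.6 (SD, n = 3). Its whole-root signal lay below the filter bound of 43.3, and set against that bound it was 26.9-fold higher, less than the 32.1-fold of AT5G35940. Of 13647 tested probe sets, 4649 were higher and 3623 lower in sorted protoplasts (limma, Benjamini-Hochberg adjusted p under 0.05), which is 60.6% of those tested. A log2 fold change of at least 1 was reached by 2449 of the higher and 2384 of the lower ones. This split was 3481 and 1896 with median centring, and 2836 and 3432 with no filter. The groups did not overlap at 75.8% of tested probe sets, against 20% by chance. The median log2 fold change of all tested probe sets was 0.15. Median centring moved it to 0.39 and the calls to 5925 higher and 2876 lower (67.3% higher, against 56.2% without centring).

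The control probe sets differed between the groups as well. The 3′/5′ signal ratio of the actin control was 24.98 ± 4.797 (SD, n = 3) in sorted protoplasts and 3.19 ± 0.153 (SD, n = 2) in whole roots. For the GAPDH control it was 6.74 ± 2.14 (SD, n = 3) against 0.879 ± 0.128 (SD, n = 2). Smaller differences were seen for a second GAPDH control (1.415 ± 0.0895 against 1.1 ± 0.0658) and for the ubiquitin control (2.78 ± 0.184 against 1.31 ± 0.301), with the same numbers of arrays. Fold change also went with gene length: across 7301 genes, Spearman's rho was 0.325, and it lay between 0.308 and 0.323 in each of the 6 pairs of a sorted and a whole-root sample. Of 4 equal groups by length, the shortest genes (median length 1369 bp) had a median log2 fold change of -0.58 and the longest (median 4183 bp) one of 0.43. These facts apply to each gene group below.

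**Figure D1:**
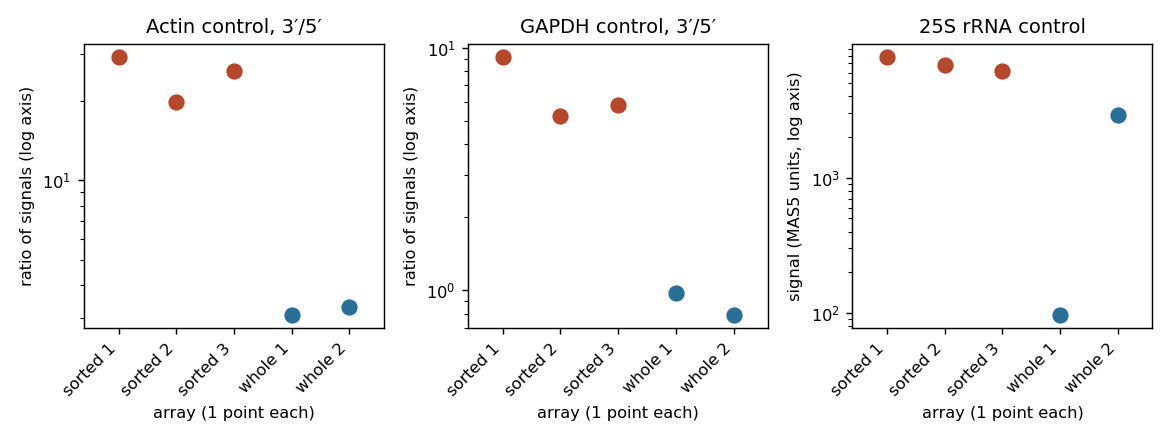
Control probe sets on each of the 5 arrays, 1 point per array, on log axes: the 3′/5′ signal ratio of the actin control, that of the GAPDH control, and the signal of the 25S ribosomal RNA control in MAS5 units. The actin ratio was between 19.8 and 29.3 in the 3 sorted samples and 3.08 and 3.295 in the whole-root samples.

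**Figure D2:**
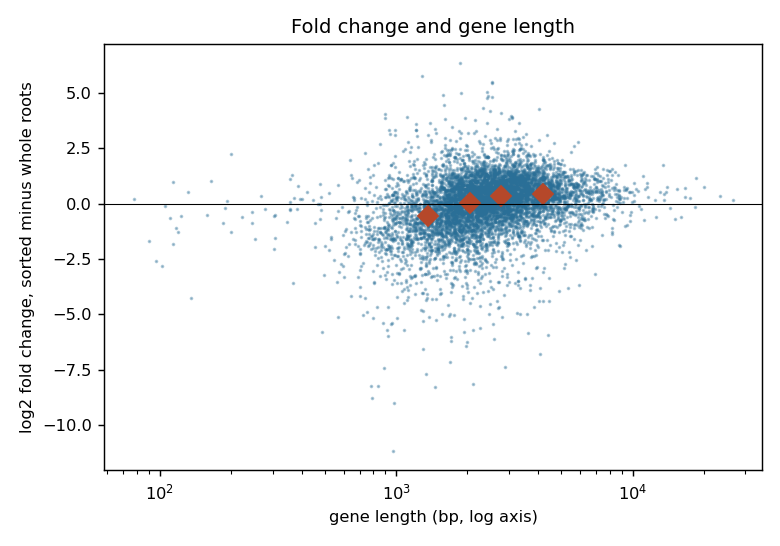
Log2 fold change (sorted protoplasts minus whole roots) against gene length in bp (log axis), 1 point per gene for 7301 genes, with diamonds at the medians of 4 equal groups by length. The median fold change went from -0.58 in the shortest group to 0.43 in the longest.

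The other large rises were those of AT3G02840 (log2 fold change 5.74, SE 0.187, limma adjusted p = 3.49e-06), AT3G45700, a transporter family gene (5.48), AT4G23590, an aminotransferase family gene (5.44), AT5G35940, a jacalin-type lectin gene (5.01), and AT5G04120 (5.00). Apart from AT5G35940 (whole-root mean 87.4), these genes had whole-root means between 6.61 and 26.3, below the filter bound, so their folds are imprecise. Set against that bound, AT3G02840 was 15.4-fold, AT3G45700 13.5-fold, AT4G23590 24.4-fold and AT5G04120 4.43-fold higher. The other large falls were those of the lipid transfer protein family genes AT3G58550 (-8.97), AT5G01870 (-8.74) and AT4G12490 (-8.24), and of AT4G23680 (-8.26) and AT5G09480 (-8.22). In sorted protoplasts these falling genes had mean signals between 4.67 and 11.7, below the filter bound of 43.3, so their folds are imprecise. Set against that bound, AT4G38080 was 110-fold, AT5G01870 68.6-fold, AT5G09480 64.8-fold and AT3G58550 64.5-fold lower, so the order below the first gene differs from that of the fitted values. Among list members named below, the same imprecision applies to the rises of WRKY53, AT1G53540, AT5G37670, CR4, XTH21, XTH16, CML38, CML30, PUB19 and scpl18. It also applies to the falls of AT1G51340, EXPA15, AT1G62510, AT1G68850, AT3G54580, ATPC1, PSBY, GSTU20 and EXPB3.

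Among stress lists fixed beforehand, all 3 tested of 5 named heat shock genes rose (3 adjusted over the list alone), with a median log2 fold change of 2.65 (camera adjusted p = 0.0202, adjusted p = 0.389 with an estimated correlation). They included AT1G53540, a small heat shock protein (3.87, SE 0.229), and AT5G48570, the peptidyl-prolyl isomerase ROF2 (2.65, SE 0.184). AT1G53540 and the list member AT5G37670 passed the filter through their sorted signals (means 212.5 and 105.7, against 14.51 and 30.45 in whole roots). The filter can therefore favour genes that rise on this list. Without sorted replicate 1 the list had a camera adjusted p of 0.0611. Of 5 tested wound and elicitor genes 2 rose and 3 did not pass (2 higher, adjusted over the list alone). Those were the transcription factor genes WRKY53 (2.95) and STZ, also called ZAT10 (1.72), and the list did not pass (camera adjusted p = 0.282). Of 4 oxidative stress genes 2 rose (2 adjusted over the list alone), the alternative NADH dehydrogenase NDB2 (1.26) and the glycosyltransferase UGT73B4 (1.06), with camera adjusted p = 0.156. The lists for jasmonate, low oxygen, abscisic acid and low pH had too few tested genes for a list test. OPCL1 of jasmonate synthesis rose (1.14), 1 of 1 tested. PDC2, a pyruvate decarboxylase of the low oxygen list, fell (-3.35) and the other tested member did not pass. COR47 fell (-0.93), 1 of 1, a call lost without whole-root replicate 1 (adjusted p = 0.0558) or 2 (adjusted p = 0.101). AT1G51340, the citrate transporter gene MATE and the tested member of the low pH list, fell (-1.66). The counts for these 4 lists were equal when adjusted over the list alone. The cytokinin response regulators and the phloem list had named members but none bright enough to be tested.

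Of 3 tested primary auxin response genes 2 fell (2 adjusted over the list alone), the auxin-conjugating enzymes GH3.3 (-4.70, SE 0.357) and WES1 (-1.76, SE 0.201). The list did not pass (camera adjusted p = 0.0516, adjusted p = 0.389 with an estimated correlation), nor did it with the length trend removed (0.0828). It passed with median centring (0.0354), quantile normalization (0.0393), and without sorted replicate 2 (0.0363), sorted replicate 3 (0.0482) or whole-root replicate 1 (0.0373). Of 7 primary wall genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), with the expansins EXPA4 (-4.17) and EXPA15 (-2.63) falling most (camera adjusted p = 0.454). Of 2 cell cycle genes 1 rose, the replication licensing factor PRL, also called MCM7 (1.31), and 1 fell. Both calls held adjusted over the list alone.

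For cell type markers the annotation left 1 or 2 tested genes per list. LHW, a vascular regulator, rose (1.34, 1 of 1), as did the receptor kinase CR4, also called ACR4, of the stem cell niche (2.13, 1 of 2). The cortex gene AT1G62510 fell (-1.10, 1 of 1), and the call was lost with the length trend removed (-0.08) and without whole-root replicate 2 (adjusted p = 0.0948). Both root hair genes did not pass (EXPA7 -0.79, adjusted p = 0.140, by limma), nor did both endodermis genes (GSO1 0.67, adjusted p = 0.133). The xylem gene GUT2 (0.31, adjusted p = 0.421) and the root cap gene AT1G65570 (0.81, adjusted p = 0.135) did not pass either. GSO1 passed after median centring (adjusted p = 0.0389), EXPA7 without sorted replicate 3 (adjusted p = 0.0330) and AT1G65570 without sorted replicate 2 (adjusted p = 0.0195). The counts for these lists were equal when adjusted over the list alone. Both planned photosynthesis genes fell (2 adjusted over the list alone), Rubisco activase RCA (-3.32) and the light-harvesting gene LHCB4.1 (-3.002). Of 5 reference genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), the ubiquitin-conjugating enzyme gene PEX4 (-2.75) and GAPC2 (-0.44). The GAPC2 call was lost after median centring (adjusted p = 0.320), with no filter (0.119), with no mean-variance trend (0.0888), and without sorted replicate 2 (0.114), sorted replicate 3 (0.162) or whole-root replicate 2 (0.296). The reference list did not pass (camera adjusted p = 0.447) and its median of -0.22 became 0.02 with median centring.

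Of 9 mitochondrion-encoded genes 6 rose, 0 fell and 3 did not pass (6 higher, adjusted over the list alone), with a median log2 fold change of 2.14 (camera adjusted p = 0.0202, adjusted p = 0.389 with an estimated correlation). They included the complex I subunits nad6 (2.71) and nad1 (2.46), but the other tested probe set of nad1 did not pass (-0.33, limma adjusted p = 0.344). Without sorted replicate 1 the list's adjusted p was 0.0767 and its median 1.38, and the call was also lost at the 60% filter (adjusted p = 0.0950). Of 62 chloroplast-encoded genes 4 rose and 27 fell (3 and 27 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00344, adjusted p = 0.497 with an estimated correlation). The photosystem genes psaJ (-4.24) and psbT (-2.83) fell most. With the length trend removed the median was 0.32 and the list did not pass (camera adjusted p = 0.111). The median length of these genes was 501 bp, against 1369 bp in the shortest of the 4 groups by length. The curve removed from them was thus fitted mostly to longer genes, so this result does not show that length accounts for their fall.

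Among the added lists, all 9 ATG8 genes fell, with a median of -1.31 (camera adjusted p = 0.000412, adjusted p = 0.521 with an estimated correlation). APG8A fell from a signal of 2229 ± 262.4 (SD, n = 2) to 298.8 ± 34.4 (SD, n = 3), and ATG8E had a log2 fold change of -2.51. Of 7 nuclear photosynthesis genes 6 fell and 1 did not pass, with a median of -3.20 (camera adjusted p = 0.00102, adjusted p = 0.521 with an estimated correlation). ATPC1 of the chloroplast ATP synthase (-3.86) and PSBY of photosystem II (-3.56) were among them. All 3 extensins fell (median -3.81, camera adjusted p = 0.0160, adjusted p = 0.521 with an estimated correlation), with AT3G54580 at -4.97 and AT1G23720 at -3.81. All 4 CYP71B genes fell (median -3.23, camera adjusted p = 0.0117, adjusted p = 0.521 with an estimated correlation), CYP71B23 by a log2 fold change of -3.85 and CYP71B26 by one of -3.44. The annotation named 19 CYP71B genes, of which these 4 were bright enough to be tested, and with no filter the list median was -0.93 (adjusted p = 0.0532). Likewise, 3 of 9 named extensins and 7 of 16 named nuclear photosynthesis genes were bright enough. AT3G54580 passed the filter through its whole-root signal (mean 384.3, against 18.1 in sorted protoplasts), so the filter can favour genes that fall. Medians of these 4 lists with the length trend removed were -1.29, -2.76, -4.24 and -3.24, and each list still passed. Of 102 cytosolic ribosomal protein genes 11 rose and 45 fell (median -0.27, camera adjusted p = 0.00634, adjusted p = 0.799 with an estimated correlation), among them AT3G49910 (-2.07) and AT3G06680 (-2.02). With the length trend removed the ribosomal median was 0.04 (adjusted p = 0.826), and without sorted replicate 1 the list's adjusted p was 0.0519.

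**Figure D3:**
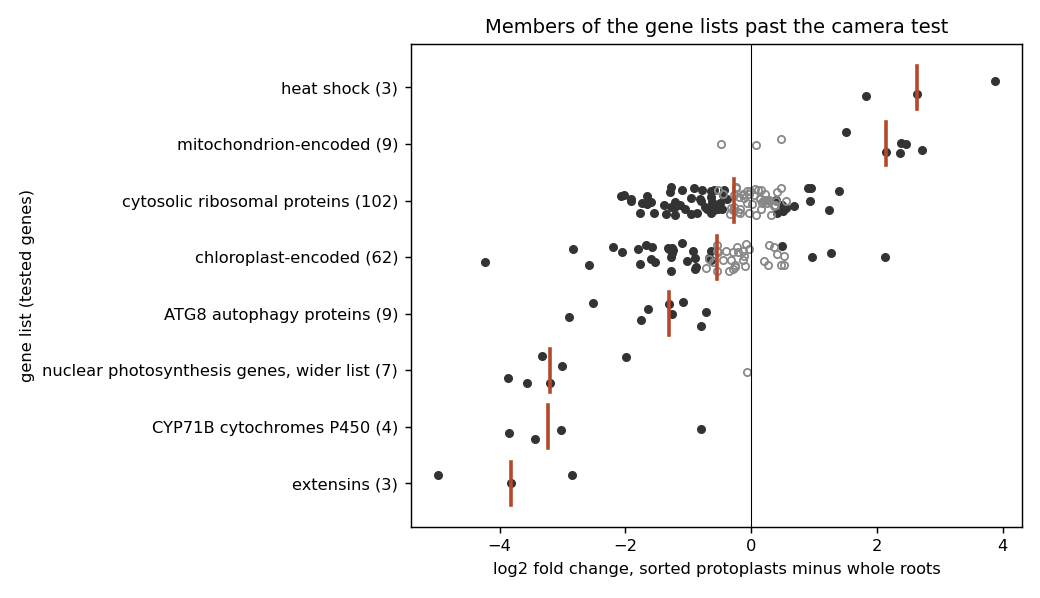
Log2 fold change (sorted protoplasts minus whole roots) of each tested member of the 8 lists past the camera test, with filled points for members past adjusted p under 0.05, open points for the others and a bar at the list median. All 9 ATG8 genes lay below 0, as did all 3 extensins and all 4 CYP71B genes.

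The other added lists did not pass camera. Of 5 small heat shock protein genes 3 rose and 2 fell (median 1.83, camera adjusted p = 0.435), and AT1G54050 rose by a log2 fold change of 3.58 while AT5G51440 (-1.31) and AT2G29500 (-0.58), named after their values were seen, fell. Of 17 trichome birefringence-like genes, which act on wall polysaccharides, 9 rose and 0 fell (adjusted p = 0.139), led by TBL39 (1.961) and TBL35 (1.71). Of 11 expansins 1 rose and 5 fell (adjusted p = 0.109), with EXPB3 at -4.53, and the list passed without sorted replicate 3 (adjusted p = 0.0371). Of 6 xyloglucan endotransglucosylases 3 rose and 1 fell (adjusted p = 0.305), with XTH21 at 4.43 and XTH16 at 3.08. Of 6 GH9 endoglucanases 3 rose and 1 fell (adjusted p = 0.663), with GH9B13 at 2.27. Of 16 serine carboxypeptidase-like genes 7 rose and 3 fell (adjusted p = 0.435), with SCPL34 at 2.39 and scpl18 at 2.01. Of 33 class III peroxidases 10 rose and 12 fell (adjusted p = 0.402), with AT1G68850 at -6.18 and AT1G49570 at -4.28. Of 5 core histones 0 rose and 3 fell (adjusted p = 0.222), and HTB2 (-1.66) and HTB1 (-1.28) did not pass with the length trend removed. Of 27 UDP-glycosyltransferases 5 rose and 6 fell (adjusted p = 0.522), with UGT72E1 at -3.67 and UGT84A4 at -2.63. Of 8 glutathione transferases 1 rose and 2 fell (adjusted p = 0.809), with GSTL3 at -3.94 and GSTU20 at -3.51. The glutathione transferase median of 0.17 and its camera direction, lower, differed in sign, as did the median and test direction of the UDP-glycosyltransferases and of the beta-glucosidases. Of 5 calmodulin-like genes 2 rose and 2 fell (adjusted p = 0.987), with CML38 at 3.62 and CML30 at 1.31, the latter call lost without whole-root replicate 1 (adjusted p = 0.0528). Of 7 U-box ligases 1 rose and 1 fell (adjusted p = 0.796), PUB19 from 16.5 ± 5.33 (SD, n = 2) to 442.3 ± 50.0 (SD, n = 3). Of 7 SWEET sugar transporters 1 rose and 3 fell (adjusted p = 0.424), with SWEET2 at -2.56 and SWEET17 at -2.05. Of 7 tetraspanins 3 rose and 3 fell (adjusted p = 0.809), with TET8 at -0.99 and TET5 at -1.09. The TET5 call was lost without whole-root replicate 2 (adjusted p = 0.0912) and with the length trend removed (adjusted p = 0.0537). Of 3 genes on the wider root hair list 1 fell, AT4G26010 (-1.52, list adjusted p = 0.305). None of 5 beta-glucosidases passed (adjusted p = 0.987 for the list), and BGLU15 had the smallest adjusted p (0.167, limma, with -0.37), which passed without sorted replicate 1 (adjusted p = 0.00364) and with the length trend removed (adjusted p = 0.0165).

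Sample preparation and RNA input went with the group in all 5 samples and cannot be separated from it, and the labels do not say whether the sorted samples were labelled in a single cycle as the whole roots were. No list call held with an estimated correlation, where the test has 3 degrees of freedom. For the heat shock and extensin lists that correlation was negative (-0.301 and -0.3315), which the setting did not allow to count. Their unadjusted camera p still went from 0.00757 to 0.0739 and from 0.0038 to 0.0613. The loss of these 2 calls was thus not due to correlation between genes.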

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

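The removal of the length trend, the comparison of plastid gene classes and the scaling test of the mitochondrion-encoded genes alone were tests chosen after the results they bear on were seen. Signals of control probe sets outside the comparisons stood above the other group. The median of 24 Bacillus control probe sets, for transcripts added as labelling controls, was 25.9 in whole-root replicate 1, 4.96 in whole-root replicate 2 and 2.00 ± 0.169 (SD, n = 3) in sorted protoplasts. The 25S ribosomal RNA control had a mean signal of 6953 ± 838.8 (SD, n = 3) in sorted protoplasts, against 96.4 and 2897 in the whole-root samples. The 5S control went the other way, at 24.0 ± 7.77 (SD, n = 3) against 192.6 ± 11.9 (SD, n = 2).

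The first pattern weighed was the breadth of the called changes. For loss of 5′ sequence in the sorted libraries, 2 probe sets of the same gene should differ about as much as unrelated ones. Over 35 genes with 2 or more tested probe sets, the median difference in log2 fold change was 1.60 within genes and 1.09 for random pairs matched on signal (95% of 2000 draws between 0.708 and 1.61), a ratio of 1.47. Positions of the probe sets along transcripts were not known, and any other disagreement between probe sets would raise the ratio too. The ratio therefore cannot single out loss of 5′ sequence, which may account for part of the calls. Gene length bias had been put down beforehand as a negative correlation below -0.3, and the measured rho of 0.325 had the opposite sign, so neither the bias as predicted nor its absence was shown. With the trend removed, 75.3% of the 4400 calls among probe sets with a gene length still passed in the same direction, which lies between the limits set for short genes as the whole cause and for its exclusion.

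The second pattern was the level of organelle transcripts. Before the data were examined, both organelle sets had been put down as higher in sorted protoplasts, and this was wrong for the chloroplast-encoded genes, which had a median of -0.54. Because that rise was absent, the test of carry-over of green tissue as its cause decides nothing. Of 7 nuclear photosynthesis genes 6 were lower and 0 higher in the sorted protoplasts (median -3.20). For these genes, this argues against more green tissue in the sorted samples than in the whole roots. Under quantile normalization the median over all organelle-encoded genes was -0.46, which decides nothing since the sets went opposite ways, while that of the mitochondrion-encoded genes went from 2.14 to 1.46, and with median centring it was 2.38, which argues against array scaling as the whole cause of their rise. Labelling and preparation stay open for this rise, and no biological explanation was tested apart from the group itself.

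The third pattern was the fall of lists with many short genes. With the length trend removed, the ATG8 median was -1.29 and the nuclear photosynthesis median -2.76. Their measured medians of -1.31 and -3.20 lay at percentiles 0.52 and 0.01 of 10000 random lists matched on length and signal. This argues against loss of signal with short gene length for both. These lengths hold introns, so loss of short transcripts was not tested. The cytosolic ribosomal median was 0.0363 and its measured median lay at percentile 52.4, so length may account for that fall. Fewer green cells in the sorted samples than in the whole roots would lower chloroplast genes of the photosynthetic complexes most. Their 24 genes lay below the 18 of plastid gene expression, with a difference of medians of -0.73, and -1.06 with the length trend removed. A two-sided permutation test across genes gave p = 0.0479 and p = 0.0089 in turn. That test counted genes as independent, but the chloroplast-encoded list had an estimated correlation of 0.438 between genes, so neither p-value decides the question. Fewer green cells remain a candidate explanation on the direction of the difference alone, with loss of such transcripts during preparation left open.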

How the results depend on the processing

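Removal of the length trend was chosen after seeing the data. No called gene that the rule for named genes chose changed sign under the alternatives run for it. The groups did not overlap at any of these genes, so leaving out a sample, a pseudocount or another filter could not have changed the sign. The alternatives did not cover the genes named as other observations, and the mitochondrial genes have no length. Of the results for named genes under alternatives, 960 kept their side of the threshold, 7 came to pass and 17 no longer passed. Of those for lists, 358 kept it, 24 came to pass, 14 no longer passed in the same direction, and 2 no longer passed and had a median of opposite sign. Those 2 were the chloroplast-encoded median (0.32) and the ribosomal median (0.0363) with the length trend removed, which takes the median trend of short genes off by construction. Medians of lists that did not pass are not counted as sign changes here; some of them lay on the other side of 0 under an alternative. Planned lists that were lower numbered 1 and went to 2 with median centring, quantile normalization, no filter (where more lists have 3 tested genes), fry or the replicate block, and to 0 with an estimated correlation or the length trend removed. Under fry the chloroplast-encoded list itself did not pass (fry adjusted p = 0.122), and the 2 lower lists were the auxin (0.00712) and reference (0.0188) lists. Planned lists that were higher numbered 2 and went to 0 with an estimated correlation and to 4 with fry. They went to 0 at the 60% filter, where the mitochondrial list did not pass and the heat shock list had too few genes to be tested, and to 1 with the length trend removed, where the mitochondrial list could not be tested. Added lists that were lower numbered 5 and went to 2 at the 60% filter, where the nuclear photosynthesis, extensin and CYP71B lists had too few genes to be tested, to 0 with an estimated correlation and to 10 with fry, and those that were higher went from 0 to 7 with fry, which does not compare a list with other genes. The 60% filter, which tests fewer probe sets, gave 2223 lower and 1273 lower by log2 1 or more. A test against log2 1 gave 735 higher and 1149 lower. With no filter the mean r was 0.85 between groups and 0.938 within whole roots. Leaving out each sample in turn gave between 3344 and 5280 higher and between 2660 and 4173 lower, between 0 (without sorted replicate 1) and 2 planned lists higher and between 1 and 2 lower. For other changes the cause was not tested. Signals near the filter bound of 43.3 limit the folds of dim genes.

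With the replicate number as a block, 3801 probe sets were higher and 3136 lower, on 1 residual degree of freedom. Replicate number 3 occurred among the sorted samples alone, so the block took up that sample. Fold changes with the block thus equalled those without sorted replicate 3 (EXPA7 -1.152 and GAPC2 -0.3715 in both), and these alternatives are not separate checks. The samples share only a number: with 2 whole-root samples the deviations of same-numbered samples correlated at 0.006 and 0.001, so the numbers were not taken as pairing. With the block, GAPC2 did not pass (adjusted p = 0.172), and EXPA7 (0.0295), GSO1 (0.0455), the expansin list (0.0330) and the auxin list (0.0383) did.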

Other observations

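The genes in this part were chosen after their values were seen and belong to no tested list, so no theme is claimed for them. Among genes with large rises, the transcription factor gene ORA47 had a log2 fold change of 3.31 (SE 0.190, imprecise since its whole-root mean of 38.7 lay below the filter bound) and the receptor kinase gene THE1, which acts in sensing the state of the wall, 2.41 (SE 0.160), from a signal of 201.1 ± 29.8 (SD, n = 2) in whole roots to 1067 ± 83.9 (SD, n = 3) in sorted protoplasts. Among large falls were FACT, an acyltransferase of suberin-associated waxes (-5.70, SE 0.283), the GDSL-type lipase family genes AT2G23540 (-8.12), AT5G37690 (-7.39) and AT1G74460 (-6.44), and the lipid transfer protein family gene AT2G48130 (-5.83). Their mean signals lay between 579.8 and 3932 in whole roots and between 8.391 and 17.78 in sorted protoplasts, where folds are imprecise. Each passed limma's test with Benjamini-Hochberg adjustment.

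Of 17 tested genes at the AT2G076 and AT2G077 loci, a stretch of chromosome that carries a copy of mitochondrial DNA, 8 were higher in sorted protoplasts, 0 were lower and 9 did not pass, with a median log2 fold change of 0.54. Probes for such copies cannot tell nuclear from mitochondrial transcripts. Of the 35 genes with 2 or more tested probe sets, both probe sets compared passed in 10, and in 4 of these they went in opposite directions.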
